A study of Homo sapiens with 4 samples.

How the data were processed

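Libraries were made from 1 µg of total RNA of SW620 cells with a directional (strand-keeping) kit, per the labels' protocols. The submitters' processing notes name STAR 2.5, a spliced read aligner, Cufflinks 2.2.1, which estimates transcript abundance, and the genome build hg38, with no role or order. The annotation release, the strand setting and any filter are not given in the sources used here. The deposited values are FPKM, fragments per kilobase of transcript scaled to the number of mapped fragments, 1 value per gene and library, and the authors' table holds 19389 rows, all marked protein-coding. FPKM from Cufflinks are estimates: reads shared between near-identical genes are split by the model, so values of histone, metallothionein, HLA and globin genes are uncertain, as are those of overlapping genes. The 4 columns sum to different totals, and low values show no steps of whole reads, so read depth could not be recovered and no count model was used. The table holds 315 positive values too small to be real abundances, which were treated as they stand. An exact 0 can be a failed estimate, so a gene at 0 is only said to be listed at 0. Symbols on 2 rows numbered 14 (28 rows), and for a listed gene the row with the higher mean was taken.

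FPKM were transformed as log2(FPKM + 1), and genes with at least 1 FPKM in at least 2 of the 4 libraries were tested, 11318 in all. Because of the pseudocount of 1, log2 changes understate the change of low genes. A gene below 1 FPKM in both controls was tested only through the treated libraries, so it could hardly appear lower, and the reverse also holds. The 2 H2O2-treated libraries were compared with the 2 controls by limma 3.58.1 in R 4.3.3, a linear model with group as its only term, and variances shrunk towards a trend with abundance. The test is two-sided, with 2 residual and 6.28 total degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all genes at a threshold of 0.05. Fold changes, SE and adjusted p for single genes come from that model unless another is named. Means are given ± SD of FPKM over the 2 libraries of a group, and log2 changes ± SE.

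Before the data were examined, 38 gene lists and 14 single genes were fixed, with the model, the alternatives and the rule for named genes. The lists cover cell division, senescence, stress responses, metabolism, colon identity and markers of leukocytes, fibroblasts, endothelial and erythroid cells. Of 997 list symbols, 966 were matched to a row, 66 of them through the Ensembl identifier of a newer symbol. The remaining symbols, 2 of the 14 single genes and the mitochondrially encoded mRNAs are not analysed here. Lists with at least 5 tested members, 34 of them, were tested with limma's camera, which compares a list with the other genes, at a preset correlation between genes of 0.01 and adjusted over the 34 lists. Camera with an estimated correlation and fry, which asks whether a list moves on balance 1 way, were run beside it. Each list was also adjusted over the list alone, gene by gene. That adjustment does not correct across the lists, and in a list of few members it lies close to the unadjusted p. A gene can count in more than 1 list. Each list's median change was set beside 10000 random lists matched on abundance, and on abundance and transcript length, with list members left out. The rule named the single genes fixed, up to 12 genes per direction past the threshold over all genes (none passed), and for each list up to 4 members with the smallest p past the list-alone test, or 2 if none passed. Other named genes are said to be chosen after their values were seen.

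Coordinates, transcript lengths and GC content come from GENCODE release 29 on hg38 (GRCh38), matched by Ensembl identifier. All identifiers were in that release, and 100% of the deposited loci overlapped the matched gene. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. The model was tested on simulated data for this comparison, with the 11318 real means, variances drawn from the fitted prior, and 200 genes changed in each of 20 draws. It called 19.4% of genes changed 2-fold, 90.4% of those changed 4-fold and 98.2% of those changed 8-fold, and 4.7% of its 2907 calls were false. A list shifted by a set amount was called in 20 of 20 draws, and 0 of 600 lists of unchanged genes were. Variances there followed the model's own prior and the libraries were drawn independently, so a low share of false calls was built in. These rates need not hold for the real libraries, where same-numbered libraries deviated together (r = 0.45 across genes). Genes were drawn independently there, so the simulation cannot show how often camera at the preset correlation calls unchanged lists whose genes move together.

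There were 17 alternatives fixed before the data were examined: other pseudocounts (0.1 and 5), no filter or a mean FPKM of at least 5, rescaling each library to the same total (TPM), upper-quartile and quantile scaling, other variance models, a replicate block, leaving out each library, summing rows of 1 symbol, and the other list tests. A further 3 were added after seeing the data: cyclic loess, removal of a trend with transcript length and GC content, and that removal together with the replicate block.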

Results

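RNA was profiled from SW620, an established human colorectal cancer cell line, in 2 groups of 2 libraries. Control cells were compared with cells exposed for 2 days to hydrogen peroxide, an oxidant. The title of the series calls the exposed cells senescent, a state in which cells stop dividing and stay metabolically active. The sample labels give the dose as 150 µM, while the series' design text gives the same figure in mM, so the unit of the dose is stated in 2 ways. The comparison asks which mRNAs differ between the control and the exposed cells, named H2O2-treated here. The deposited table gives FPKM for 19389 protein-coding genes, and read depth is unknown because it holds no counts. Summed FPKM was 695837 and 660860 in control libraries 1 and 2, and 574782 and 617668 in H2O2-treated libraries 1 and 2. Genes above 0 numbered 14563 and 14716 in the controls and 15371 and 15828 in the treated libraries. Across the 11318 genes tested, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.988 between the controls and 0.968 between the treated libraries, and 0.964 to 0.981 between libraries of different groups. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

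H2O2-treated cells had higher levels of some genes for secreted factors associated with senescence, among them AREG, IL11 and PLAU. They had lower levels of some genes for nuclear lamina and chromatin proteins, among them LMNB1, HMGB2, H2AFX and H2AFZ. These 7 genes passed limma's test adjusted over their list alone. Over all 11318 genes, limma called 0 genes higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1260 genes, 704 higher and 556 lower, where 565.9 would be the average if no gene changed. Splitting the same libraries by number instead gave 830 such genes and the crossed split 37, so counts from other splits lay on both sides of 565.9. The smallest adjusted p, 0.0511, was shared by 7 genes, all higher in treated cells, and 22 genes, all higher, had an adjusted p under 0.1. Named after their values were seen, the 7 include AKAP12, a scaffold protein of kinase A, at 15.6 ± 0.682 FPKM in controls and 79.5 ± 6.99 FPKM in treated cells (SD, n = 2). APOE, a lipid carrier, went from 10.2 ± 1.04 to 53.5 ± 10.7 FPKM, and IGF2, a growth factor, from 4.47 ± 1.39 to 26.9 ± 2.07 FPKM. With 1 library left out, the lone library of its group being assumed to vary like the other group, the calls were 30 higher and 3 lower without control 1, 8 and 0 without control 2, 127 and 13 without treated 1, and 22 and 9 without treated 2. Rescaling each library to the same total (TPM) called 32 genes higher and 0 lower, and moved the median change of all genes by 0.172 on the log2 scale.

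Of the 14 genes fixed before the data were examined for their known link to senescence or oxidative stress, 12 were measured and none passed over all genes. CDKN1A, a cyclin-dependent kinase inhibitor and p53 target at chromosome 6, 36676460 to 36687339 (hg38), stood at 1.36 ± 0.149 FPKM in controls and 5.66 ± 2.62 FPKM in treated cells (SD, n = 2). Its log2 change was 1.44 ± 0.30 (SE; adjusted p = 0.247), and it rose when adjusted over the list alone, both among the cyclin-dependent kinase inhibitors and among the p53 targets. Over all genes CDKN1A passed without treated 1 (log2 change 1.85; adjusted p = 0.0225), and not without another library. LMNB1, the lamin B1 gene at chromosome 5, 126776623 to 126837020, stood at 99.1 ± 8.88 and 55.5 ± 0.453 FPKM, a log2 change of -0.82 ± 0.16 (SE; adjusted p = 0.242). HMGB2, a chromatin protein, had 280.4 ± 18.7 and 151.5 ± 49.7 FPKM, with a log2 change of -0.92, or -0.58 without treated 1. The stress cytokine GDF15 had 109.4 ± 0.139 and 175.1 ± 47.1 FPKM, and the chemokine CXCL8 had 8.54 ± 3.27 and 15.5 ± 5.76 FPKM. The tumour suppressor gene CDKN2A had a log2 change of -0.14, whose sign turned under rescaling to TPM, quantile normalization and cyclic loess, and without control 1 (0.07). Of the oxidant defence genes, HMOX1 was at 1.35 ± 0.395 and 2.59 ± 1.75 FPKM, NQO1 at 217.2 ± 7.17 and 224.8 ± 72.3 FPKM, and CAT at 26.8 ± 2.86 and 23.1 ± 12.3 FPKM. The log2 change of NQO1 (0.01) was -0.02 without control 1 and -0.32 without treated 2, and that of CAT (-0.30) was 0.25 without treated 1. That of HMOX1 (0.53) was 1.05 without treated 1 and 0.01 without treated 2, that of CXCL8 (0.79) was 0.43 without control 1 and 0.42 without treated 2, and that of GDF15 (0.65) was 0.37 without treated 1. IL6 was listed at 0 in all 4 libraries.

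Secreted factors associated with senescence were higher as a list. Of 26 members tested, 11 rose when adjusted over the list alone, 0 fell, and 15 did not pass, while 23 had a positive change. The largest change among them belonged to AREG, a ligand of the epidermal growth factor receptor, at 2.16 ± 0.333 FPKM in controls and 13.1 ± 2.28 FPKM in treated cells (SD, n = 2; log2 change 2.15). The cytokine IL11 rose from 0.716 ± 0.103 to 5.29 ± 0.339 FPKM, and the urokinase gene PLAU from 3.73 ± 0.451 to 11.3 ± 0.653 FPKM. IL11, below 1 FPKM in both controls, met the filter only through the treated libraries. Also past that test, and named after their values were seen, were IGFBP3, EREG, SERPINE2, PLAUR, ICAM1, MMP14 and TIMP2. The median log2 change of the list was 0.73, with a camera adjusted p of 3.94e-12 at a preset correlation between genes of 0.01. The adjusted p was 0.407 with an estimated correlation, which over 2 residual degrees of freedom called 0 of 34 lists, 3 of them at an unadjusted p under 0.05. Without control 1, 10 of the 11 genes passed, without control 2, 8 passed, and all 11 passed without either treated library. Without a filter on low values the list's median was 0.19. Immediate-early genes, which growth signals switch on within minutes, were also higher as a list. DUSP5, a phosphatase that acts on ERK, rose from 4.94 ± 1.22 to 23.9 ± 3.37 FPKM, and EGR3, JUNB and FOSB also rose, 4 of 24 members when adjusted over the list alone. The median log2 change of that list was 0.50 (camera adjusted p = 1.23e-07; adjusted p = 0.407 with an estimated correlation). Of the 4 genes, 3 passed without control 1, 2 without control 2 and 2 without treated 2. Among NF-kB targets, NFKB2, ICAM1 and TNFAIP2 rose, 3 of 15 members, and the list's median log2 change was 0.34 (camera adjusted p = 0.000781; adjusted p = 0.648 with an estimated correlation). Of these 3 genes, 1 passed over the list alone without control 1 and 0 without control 2 or treated 2. The median of NF-kB targets was 0.15 with a pseudocount of 5, 0.17 after quantile normalization, 0.19 after cyclic loess, 0.20 at a mean FPKM of at least 5, 0.21 with no filter and 0.53 after rescaling to TPM, and the call stood in each.

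In the same libraries some markers of other cell types moved with treatment. CD68, a lysosomal membrane protein abundant in macrophages, rose from 1.87 ± 0.064 to 12.7 ± 7.13 FPKM, 1 of 4 leukocyte markers tested. THY1 rose among the 5 fibroblast markers tested, from 0.26 ± 0.143 to 1.65 ± 0.396 FPKM. TIE1, a receptor of endothelial cells, rose from 0.0966 ± 0.00351 to 1.94 ± 0.386 FPKM and EGFL7 from 7.41 ± 1.65 to 12.4 ± 1.91 FPKM, the 2 endothelial markers tested, each adjusted over the list alone. For EGFL7 the limma p was 0.0184 both unadjusted and over that list, and 0.366 adjusted over all genes. THY1 and TIE1 were below 1 FPKM in both controls and met the filter only through the treated libraries, so only a rise could be seen in them. The endothelial gene PECAM1, at or below 0.136 FPKM in each library, was too low to be tested and showed no rise. THY1 did not pass without control 2, and EGFL7 did not pass without control 2 or treated 2. The erythroid marker HBA1 had 5.10 ± 2.27 and 6.74 ± 4.10 FPKM. The fibroblast list was not called (median log2 change 0.33; camera adjusted p = 0.0768) except without control 2 (0.42) or treated 1 (0.66), and the other marker lists were too small for a list test. COL1A1, which fibroblasts make in large amounts, had 2.44 ± 1.01 and 2.15 ± 1.29 FPKM, and the leukocyte gene PTPRC was at or below 0.00822 FPKM in each library.

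**Figure D1:**
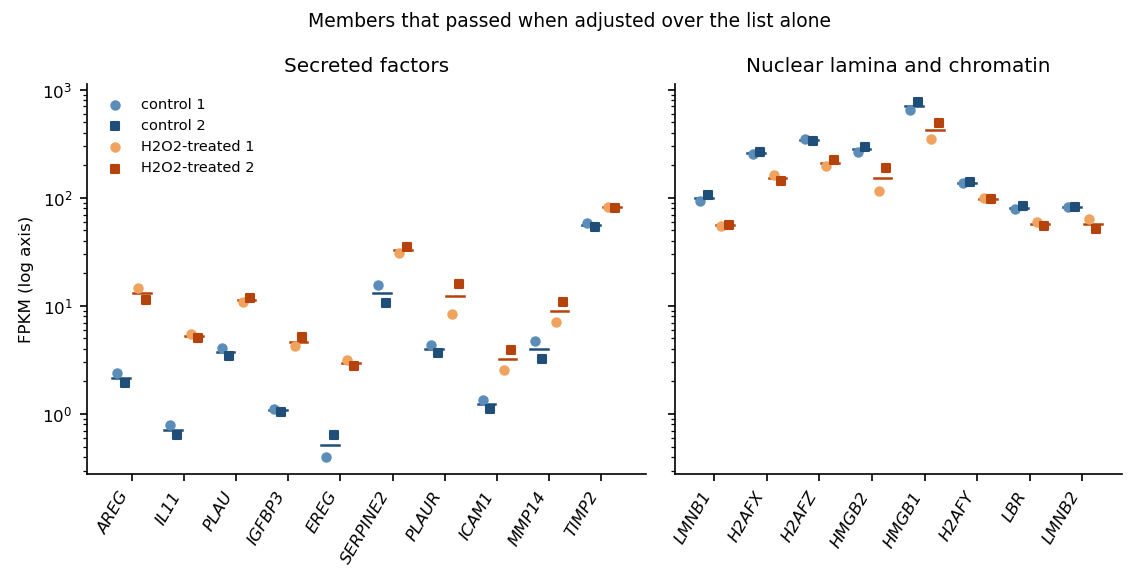
FPKM on a log axis in each of the 4 libraries for members of 2 gene lists that passed when adjusted over the list alone, secreted factors on the left and nuclear lamina and chromatin genes on the right. Points are libraries and short lines are group means (n = 2); AREG went from 2.16 to 13.1 FPKM and LMNB1 from 99.1 to 55.5 FPKM.

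Genes of the nuclear lamina and of chromatin proteins, chosen as markers of senescence, were lower as a list. Of 14 members, 8 fell when adjusted over the list alone and 0 rose. They were LMNB1, the histone variant genes H2AFX and H2AFZ, HMGB2, and, named after their values were seen, HMGB1, H2AFY, LBR and LMNB2. H2AFX fell from 259.1 ± 8.21 to 151.9 ± 14.1 FPKM and H2AFZ from 339.3 ± 10.9 to 209.9 ± 18.6 FPKM (SD, n = 2). The median log2 change was -0.49 (camera adjusted p = 1.95e-05; adjusted p = 0.438 with an estimated correlation), and fry, which asks whether a list moves 1 way on balance, called this list alone of the 34 (adjusted p = 0.0494). Among other settings, the fry call was lost without control 1 (adjusted p = 0.12), control 2 (0.14), treated 1 (0.296) or treated 2 (0.278), with a pseudocount of 0.1, and after rescaling to TPM, upper-quartile, quantile or loess normalization, over a range of 0.0347 to 0.334 in all alternatives. Without control 1 or control 2, 0 of the 8 passed over the list alone, while 7 passed without treated 1 and 5 without treated 2. The median was -0.30 after rescaling to TPM and -0.32 after cyclic loess.

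DNA replication genes were lower as a list, with a negative change in 38 of 38 members. The ligase gene LIG1 had 13.5 ± 0.921 FPKM in controls and 8.46 ± 0.735 FPKM in treated cells, and the flap endonuclease gene FEN1 had 109.6 ± 7.67 and 75.3 ± 6.14 FPKM (SD, n = 2). By limma, 0 of the 38 passed when adjusted over the list alone, and 8 were lower at an unadjusted p under 0.05. The list's median log2 change was -0.27 (camera adjusted p = 3.11e-06; adjusted p = 0.648 with an estimated correlation), and it was -0.41 without control 1, -0.11 without control 2, -0.09 after rescaling to TPM and -0.18 after cyclic loess. Mitosis and spindle genes were also called lower, with a median log2 change of -0.35 over 33 members (camera adjusted p = 0.000781; adjusted p = 0.763 with an estimated correlation), of which 0 passed by limma over the list alone and 2 were lower at an unadjusted p under 0.05. The 2 with the smallest p were CENPF, a kinetochore protein gene at 33.4 ± 3.59 and 23.4 ± 4.22 FPKM, and ECT2, a regulator of cytokinesis at 77.0 ± 19.8 and 48.8 ± 12.3 FPKM. This call rested on treated 1. Against the control mean the median was -0.70 in treated 1 and 0.13 in treated 2, and without treated 1 the direction turned, while without treated 2, 28 members passed over the list alone. Without control 2 the median was -0.18 and the call was lost. It was -0.17 after rescaling to TPM and -0.22 after cyclic loess. Core histone genes, whose mRNAs lack a poly(A) tail when cells replicate DNA, went both ways. HIST1H3H rose from 0.804 ± 0.144 to 2.88 ± 0.458 FPKM, HIST1H2AG and HIST2H2BE also rose, and HIST1H2BL fell from 2.58 ± 0.0846 to 0.826 ± 0.12 FPKM, 4 of 20 members when adjusted over the list alone. HIST1H3H was below 1 FPKM in both controls, and HIST1H2BL in both treated libraries. Each met the filter through the other group only, so its direction was set by the filter. The list's median log2 change was 0.31 (camera adjusted p = 0.0143; adjusted p = 0.648 with an estimated correlation), and the call was lost without treated 2 (0.17), with no filter (0.08), with a mean FPKM of at least 5 (0.20), after rescaling to TPM (0.49), and after quantile (0.20) or loess (0.21) normalization. Of the 4 genes, 0 passed without either control and 3 without treated 1. Homologous recombination and Fanconi genes were not called (21 members; camera adjusted p = 0.903), but were called lower without control 1 (median -0.17) and higher without control 2 (0.19), with XRCC2 at 7.46 ± 1.73 and 10.7 ± 3.25 FPKM and BARD1 at 5.35 ± 1.24 and 3.76 ± 1.11 FPKM.

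**Figure D2:**
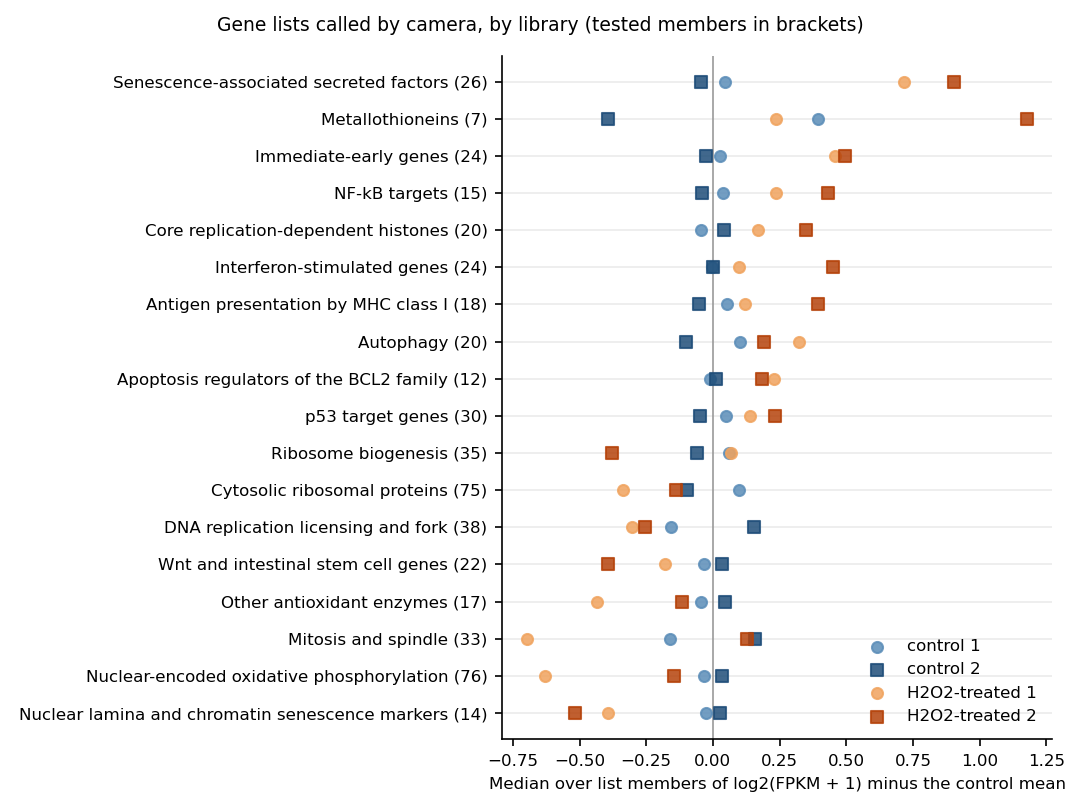
Median over list members of log2(FPKM + 1) minus the control mean, for the 18 lists called by camera at a preset correlation of 0.01. Each point is 1 library, blue for controls and orange for H2O2-treated; secreted factors lay at 0.72 and 0.90 in treated libraries 1 and 2, while mitosis and spindle genes lay at -0.70 and 0.13.

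Targets of p53 went both ways around CDKN1A. Besides its rise, TP53I3, a p53-induced oxidoreductase gene, fell from 18.0 ± 0.391 to 10.03 ± 0.458 FPKM (SD, n = 2), and these were the 2 of 30 members that passed over the list alone. The list was called higher with a median log2 change of 0.15 (camera adjusted p = 0.0263; adjusted p = 0.648 with an estimated correlation), and lost that call without control 2 (0.13), without treated 2 (0.14) and with no filter (0.15). The median was 0.23 without treated 1, 0.10 with a pseudocount of 5, 0.07 after quantile normalization, 0.02 at a mean FPKM of at least 5 and 0.33 after rescaling to TPM. Without either control, 0 of the 2 genes passed over that list. Among the cyclin-dependent kinase inhibitor and RB genes, CDKN1A was the 1 of 10 that rose, and the list was not called (camera adjusted p = 0.676). Among BCL2 family genes, BOK, a pro-apoptotic member, rose from 1.48 ± 0.647 to 4.22 ± 0.321 FPKM, 1 of 12. That list's median log2 change was 0.15 (camera adjusted p = 0.0366; adjusted p = 0.648 with an estimated correlation), and its call was lost without control 2 (0.14), treated 1 (0.18) or treated 2 (0.23), with no filter and at a mean FPKM of at least 5. It was 0.23 to 0.34 under the other scalings. BOK did not pass without control 2 or treated 1.

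Oxidant defence genes did not move together. Of 29 targets of NRF2, the main regulator of antioxidant genes, 13 had a positive and 16 a negative change, with a median log2 change of -0.04 (camera adjusted p = 0.987). By limma 0 passed over the list alone and 1 was higher at an unadjusted p under 0.05, ABCC3, an export pump, at 4.86 ± 0.349 and 8.85 ± 0.981 FPKM (SD, n = 2). TALDO1, next by p, lay lower at 179.0 ± 0.114 and 133.6 ± 25.6 FPKM. Other antioxidant enzymes were called lower (17 members; median log2 change -0.32; camera adjusted p = 0.0366; adjusted p = 0.745 with an estimated correlation), although the 2 with the smallest p, the peroxidase genes GPX8 and GPX3, lay higher in treated cells. By limma 0 of the 17 passed over the list alone, with 2 higher and 1 lower at an unadjusted p under 0.05. Random lists matched on abundance and transcript length had a median of -0.183 (central 95%, -0.327 to -0.0474). That range covers this list's -0.319, so the fall does not set it apart from such genes. The call was lost without control 1 (-0.28), control 2 (-0.26) or treated 1 (-0.12), and after quantile (-0.13), loess (-0.09) or length and GC (-0.24) correction, and the median was -0.14 after rescaling to TPM. Metallothioneins, which bind zinc and copper, had a positive change in 7 of 7 members, with a median log2 change of 0.71 (camera adjusted p = 0.00234; adjusted p = 0.648 with an estimated correlation). MT1G had 18.2 ± 10.5 and 40.4 ± 7.02 FPKM and MT1E 39.0 ± 18.9 and 76.1 ± 25.8 FPKM. By limma 0 passed over the list alone and 2 were higher at an unadjusted p under 0.05. Without treated 2 the median was 0.24 and the call was lost, and without treated 1 it was 1.18. Targets of ATF4, a stress-activated transcription factor, were not called (35 members; camera adjusted p = 0.581), and the treated libraries stood apart, at medians of 0.51 in treated 1 and -0.90 in treated 2 against the control mean. The list was called lower without treated 1 or control 2 (-0.46), higher without treated 2 or control 1 (0.11), and lower after rescaling to TPM (0.01). PPP1R15A, a regulator of the same response and the 1 member at an unadjusted p under 0.05, was at 28.4 ± 5.49 FPKM in controls and 49.1 ± 18.3 FPKM in treated cells. By limma 0 of the 35 passed over the list alone. The amino acid transporter gene SLC7A5 was at 293.4 ± 52.7 FPKM in controls and 209.4 ± 153.7 FPKM in treated cells. The unfolded protein response (median log2 change 0.02), heat shock (-0.10), and iron and ferroptosis (-0.01) lists were not called, except the first without treated 1 (-0.21).

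Nuclear-encoded genes of oxidative phosphorylation, the mitochondrial chain that makes ATP, were lower as a list, with a negative change in 72 of 76 members. The complex I genes NDUFA7 and NDUFB2 had 98.7 ± 5.15 and 175.5 ± 15.1 FPKM in controls against 60.8 ± 10.8 and 104.0 ± 26.7 FPKM in treated cells (SD, n = 2). By limma 0 of the 76 passed over the list alone and 11 were lower at an unadjusted p under 0.05. The list's median log2 change was -0.41 (camera adjusted p = 2.51e-12; adjusted p = 0.648 with an estimated correlation). It was -0.63 in treated 1 and -0.14 in treated 2 against the control mean, and without treated 2, 51 members passed over the list alone. The median was -0.23 after rescaling to TPM, -0.23 after quantile normalization and -0.18 after cyclic loess. Cytosolic ribosomal protein genes had a negative change in 71 of 75 members, with RPS15 at 2665 ± 26.3 FPKM in controls and 1730 ± 358.1 FPKM in treated cells. Their median log2 change was -0.23 (camera adjusted p = 2.75e-06; adjusted p = 0.745 with an estimated correlation), by limma 0 passed over the list alone, and 2 were lower at an unadjusted p under 0.05. The median turned to 0.02 after quantile normalization and 0.05 after cyclic loess, and was -0.14 without control 1 or without treated 1, -0.05 after rescaling to TPM, -0.15 after upper-quartile scaling and -0.12 after length and GC correction. Across genes, the change fell with abundance (Spearman's rho = -0.374 over 11318 genes) and was higher in longer transcripts (rho = 0.235 over 11312 genes). Ribosome biogenesis genes, among them GAR1 at 36.2 ± 0.650 and 26.4 ± 2.58 FPKM, were called lower with a median log2 change of -0.08 (35 members; camera adjusted p = 0.0474; adjusted p = 0.791 with an estimated correlation). By limma 0 of them passed over the list alone and 2 were lower at an unadjusted p under 0.05. Random lists matched on abundance and transcript length had a median of -0.116 (central 95%, -0.211 to -0.0266). That range covers this list's -0.08, so the fall does not set it apart from such genes. The call was lost without control 1 (-0.01), without treated 2 (0.07), at a mean FPKM of at least 5, and after rescaling to TPM (0.10), upper-quartile (-0.00417), quantile (-0.02) or loess (0.02) normalization. The median was -0.24 without control 2 and -0.38 without treated 1.

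**Figure D3:**
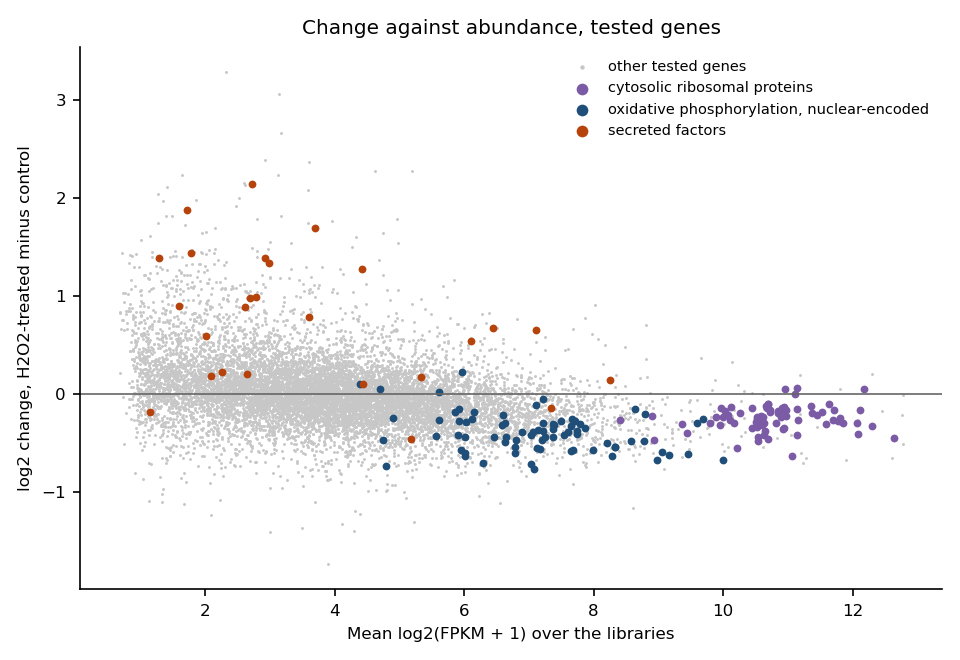
Log2 change between H2O2-treated and control libraries against mean log2(FPKM + 1) over the 4 libraries, 1 point per gene over 11318 genes tested. Secreted factors lie above 0 at low to middle abundance, while most of the 76 oxidative phosphorylation genes and the 75 ribosomal protein genes lie below 0 at high abundance, ribosomal protein genes turning to a median of 0.05 after cyclic loess.

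Interferon-stimulated, MHC class I and autophagy genes were called higher as lists, each with 1 member past the test over the list alone. Among 24 interferon-stimulated genes, ISG20, an antiviral exonuclease gene, rose from 3.9 ± 1.31 to 10.2 ± 0.479 FPKM (SD, n = 2), the 1 member past the test over the list alone. That list's median log2 change was 0.29 (camera adjusted p = 0.000499; adjusted p = 0.648 with an estimated correlation), and without treated 2 it was 0.10 and the call was lost. It was 0.45 without treated 1, 0.18 with a pseudocount of 5, 0.19 after quantile normalization and 0.48 after rescaling to TPM. Among 18 genes of antigen presentation by MHC class I, HLA-B rose from 14.8 ± 5.998 to 47.2 ± 10.6 FPKM, again the 1 member past the test, and the list's median log2 change was 0.27 (camera adjusted p = 0.000676; adjusted p = 0.648 with an estimated correlation). After rescaling to TPM that median was 0.45. Without treated 2 it was 0.12, and neither the list nor HLA-B passed. ISG20 did not pass over its list without control 2 or treated 2. Autophagy genes had a median log2 change of 0.24 over 20 members (camera adjusted p = 0.000676; adjusted p = 0.648 with an estimated correlation). MAP1LC3A, which coats autophagosomes, was the 1 that rose over the list alone, from 1.92 ± 0.821 to 6.44 ± 1.45 FPKM, and did not pass without control 2 or treated 2. The median of autophagy genes was 0.42 after rescaling to TPM. The lysosome list was not called (34 members; median log2 change 0.06; camera adjusted p = 0.0961) except without control 2 (0.10) or treated 1 (0.25), at a mean FPKM of at least 5 (0.05), and after quantile (0.13) or loess (0.15) normalization, with the protease genes CTSH at 3.32 ± 0.119 and 7.04 ± 3.12 FPKM and CTSB at 88.9 ± 33.7 and 146.7 ± 14.7 FPKM.

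Wnt pathway and intestinal stem cell genes were lower as a list. SMOC2, a matrix protein gene of intestinal stem cells, fell from 38.6 ± 5.06 to 19.0 ± 0.381 FPKM (SD, n = 2), the 1 of 22 members past the test over the list alone. The median log2 change was -0.28 (camera adjusted p = 0.0156; adjusted p = 0.648 with an estimated correlation), and the call was lost without control 2 (-0.24) and without treated 2 (-0.18). It was -0.10 after rescaling to TPM. SMOC2 did not pass over the list without either control. Genes of epithelial-mesenchymal transition went both ways, with the integrin gene ITGA5 and the transcription factor gene TWIST2 rising and the matrix genes TNC and FN1 falling, each adjusted over the list alone among 14 members. TWIST2, below 1 FPKM in both controls, met the filter only through the treated libraries, so only a rise could be seen in it. TNC fell from 18.5 ± 5.21 to 8.08 ± 2.74 FPKM and ITGA5 rose from 5.70 ± 1.84 to 12.1 ± 1.94 FPKM. None of these 4 passed without control 2, TWIST2 did not pass without control 1, and FN1 did not pass without treated 1 (-0.70). Among the 14 TGF-beta targets, JUNB and LTBP3 rose when adjusted over the list alone. JUNB did not pass without control 2, and LTBP3 did not pass without control 1, control 2 or treated 1. PTPN14, which restrains YAP, fell from 15.1 ± 0.503 to 8.39 ± 0.342 FPKM, 1 of 15 YAP and TEAD targets, and did not pass without either control. Camera called none of these 3 lists (adjusted p = 0.541, 0.0596 and 0.235), nor the list of enterocyte and goblet cell genes (5 members; adjusted p = 0.557), hypoxia and glycolysis (0.0596), cholesterol synthesis (0.0594) or fatty acid synthesis (0.41). Hypoxia and glycolysis genes were called higher without treated 1 (0.19) and after quantile (0.19) or loess (0.21) normalization. TGF-beta targets were called higher without control 1 (0.36) or treated 1 (0.23), at a mean FPKM of at least 5 (0.35), and after quantile (0.06), loess (0.09) or length and GC (0.30) correction. Cholesterol synthesis genes were called lower without control 1 (-0.41) or treated 2 (-0.34), with no filter (-0.22), after rescaling to TPM (-0.05) and after upper-quartile scaling (-0.14), and fatty acid synthesis genes without control 1 (-0.24). The median, the mean and the test differed in sign for the cyclin-dependent kinase inhibitor, unfolded protein response, homologous recombination, and iron and ferroptosis lists, none of them called.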

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

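The cyclic loess, length and GC, and combined block settings were chosen after the data were seen, and the others before. Single genes were recomputed only if fixed beforehand, among the smallest p of their list, or among the 22 with an adjusted p under 0.1. All but the fixed genes were picked by their p in these data, so the counts do not describe genes at large. Of the recomputed log2 changes of single genes, 1464 kept their direction and side of the threshold, 206 newly passed and 14 changed sign. Of those of list medians, 501 kept direction and call, 30 newly passed, 32 lost a call, and 40 changed sign or camera direction without a reversed call, and 7 reversed. A mean FPKM of at least 5 called 5 genes higher, all by at least 2-fold, and rescaling to TPM called 32 higher, 32 by at least 2-fold, among them 22 of the 22 genes with an adjusted p under 0.1. The cause was not tested. Camera with an estimated correlation called 0 lists and fry 1, against 18. Leaving out 1 library gave 8 to 127 genes higher and 0 to 13 lower, with 8 to 127 and 0 to 13 by at least 2-fold; a lone library is assumed to vary like the other group. The replicate block, which treats same-numbered libraries as pairs, called 397 genes higher and 190 lower (201 and 19 by at least 2-fold), and with the length and GC trend removed 177 and 71 (138 and 20), and fry did not call the lamina and chromatin list under either. Same-numbered libraries deviated together from their group means (r = 0.45 across genes), but 2 pairs do not establish a pairing, and the labels give none. Splitting the 4 libraries by number gave 0 calls by limma, with 830 genes at an unadjusted p under 0.05, and the crossed split gave 0 with 37. Ribosomal proteins reversed to a median of 0.0154 under quantile normalization and 0.0513 under cyclic loess. Without 1 library, medians ranged from -0.90 to 0.51 for ATF4 targets, -0.17 to 0.19 for homologous recombination genes, -0.70 to 0.13 for mitosis genes and -0.38 to 0.0685 for ribosome biogenesis, since the libraries of a group differ in these lists. Depth is unknown, so no limit from counting error can be given.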

Other observations

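Gene families, which share a symbol prefix, were grouped after the data were seen (196 families of at least 8 tested genes). Camera at a preset correlation called 7 families higher and 12 lower, of which 12 lay outside the central 95% of lists matched on abundance and transcript length; with an estimated correlation camera called 0, and 0 had an unadjusted p under 0.05. Mitochondrial ribosomal proteins of the large subunit (MRPL) were lower, with a negative change in 47 of 49 genes (13 at an unadjusted p under 0.05), a median log2 change of -0.34 and an adjusted p of 2.08e-10 (0.836 with an estimated correlation). Matched lists had a median of -0.20 (-0.29 to -0.12), and the call held under each other scaling, at -0.16 after rescaling to TPM, -0.21 after quantile normalization and -0.19 after cyclic loess. MRPL23 had 152.4 and 144.5 FPKM in controls 1 and 2 against 88.3 and 92.6 FPKM in treated libraries 1 and 2. SRSF splicing factors were called lower as a family, with a negative change in 10 of 11 genes (5 at an unadjusted p under 0.05) and a median of -0.41 (adjusted p = 0.00439; 0.836 with an estimated correlation), a call lost after quantile (-0.23) or loess (-0.23) normalization and without treated 2 (-0.35), with a median of -0.62 without treated 1 and -0.23 after rescaling to TPM. SRSF3 had 232.4 and 202.5 FPKM in controls 1 and 2 against 139.9 and 126.4 FPKM in treated libraries 1 and 2.

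HLA genes, which present peptides to T cells and include class II members, were called higher as a family, with a positive change in 8 of 8 (4 at an unadjusted p under 0.05) and a median log2 change of 0.58 (adjusted p = 0.00205; 0.836 with an estimated correlation) that was 0.32, with the call lost, without treated 2 and 0.94 without treated 1. HLA-DQB1, a class II gene, had 2.36 and 2.44 FPKM in controls 1 and 2 against 4.41 and 8.50 FPKM in treated libraries 1 and 2. The leukocyte markers CD68 (7.65 and 17.7 FPKM) and LYZ (4.41 and 18.4 FPKM) were also higher in treated 2 than in treated 1, while PTPRC was at 0.00822 FPKM in treated 1 and listed at 0 in treated 2. Interleukin and interleukin receptor genes (IL) were called higher as a family, with a positive change in 23 of 25 (7 at an unadjusted p under 0.05) and a median of 0.25 (adjusted p = 0.000546; 0.836 with an estimated correlation), and lost the call after quantile (0.16) or loess (0.17) normalization, with 0.43 without treated 1 and 0.44 after rescaling to TPM. IL15RA, a receptor subunit, had 0.632 and 0.164 FPKM in controls 1 and 2 against 2.196 and 2.183 FPKM in treated libraries 1 and 2. IL15RA, IL11, IL2RG and IL32, all at an unadjusted p under 0.05, were below 1 FPKM in both controls. They met the filter only through the treated libraries, so only a rise could be seen in them. The family was not run without that filter.

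Of the tests below, those on matched lists for oxidative phosphorylation, ribosomal proteins and secreted factors, on a uniform background and on same-numbered libraries were chosen only after the result was seen. Secreted factors were called higher as a list (median log2 change 0.73), though not with an estimated correlation (adjusted p = 0.407; 0 of 34 lists called, 3 at an unadjusted p under 0.05). Matched random lists had a median of -0.0337 (-0.16 to 0.11), which argues against a trend with abundance and transcript length, and a uniform background in the treated libraries would add the same to each gene, yet the members gained a median of 4.96 FPKM where the 99th percentile of gain over 5843 genes near 0 in controls was 0.305 FPKM. Abundant transcripts of fibroblasts, endothelial cells and leukocytes (COL1A1, COL1A2, COL3A1, DCN, PECAM1, PTPRC) together changed by -0.275 FPKM, against a gain of 106.0 FPKM over the 11 members that passed. COL1A1 alone changed by -0.292 FPKM, the other transcripts stayed near 0, and the 11 members were picked by their rise in these data. Those transcripts gave no sign of such cells as the source of the whole gain, but markers that rose were outside the sum, so a part stays open. Other markers from the same lists, named after their values were seen and present in controls too, had higher means in treated libraries: CD68 (1.87 and 12.7 FPKM), EGFL7 (7.41 and 12.4 FPKM), and, through treated 2 alone, FBLN1 (31.8 FPKM in controls, 32.8 in treated 1 and 56.4 in treated 2) and LYZ (3.69, 4.41 and 18.4 FPKM). A response of the cells to the treatment, which the design names, stays open and was not tested apart from these.

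Oxidative phosphorylation and cytosolic ribosomal protein genes, both abundant and short, were called lower, though not with an estimated correlation (adjusted p = 0.648 and 0.745). Matched lists had a median of -0.239 (-0.30 to -0.18) for oxidative phosphorylation, short of its -0.41, so that trend is not the whole of it. For ribosomal proteins matched lists had a median of -0.297 (-0.37 to -0.23), which covers the observed -0.23, so the trend is a candidate explanation for that list. The oxidative phosphorylation list's median against the control mean was -0.63 in treated 1 and -0.14 in treated 2. Matched lists were not drawn per library, so the share of each library in the excess is not known. A difference between the treated libraries and an effect of the treatment both stay open, the latter untested.

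Treated libraries 1 and 2 lay apart in mitosis genes (median of treated 2 minus treated 1, 0.82) and in ATF4 targets (-1.43). A trend with abundance and transcript length falls short of this, as matched lists had medians of -0.0593 (-0.21 to 0.09) for mitosis genes and -0.04 (-0.18 to 0.11) for ATF4 targets. The controls differed the same way, control 2 minus control 1 being 0.32 for mitosis genes and -0.638 for ATF4 targets, so something shared by same-numbered libraries, such as a culture or a day, could account for part of it. The gap was wider between the treated libraries than between the controls, and what else adds to it stays open.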
